A study of Mus musculus with 4 samples.

How the data were processed

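Single-cell RNA was measured in 4 libraries from Il33 reporter mice (genotype B6.Il33mCherry/mCherry on C57BL/6), 1 library in each of 4 groups. Per the labels, 3 libraries came from lung and 1 from gonadal adipose tissue given as female, all given as CD45-negative (without that leukocyte surface protein). The labels give the 10x Chromium 3' v1 kit. Per the submitters' processing notes, Cell Ranger was used with the mouse genome build mm10. Its version is not given in the sources used here, nor are the gene annotation or the rule by which barcodes were called cells. The deposited matrices hold unnormalized UMI counts (whole numbers of distinct molecule tags) for 27998 genes and every listed barcode. No other processed values were used here, and the labels do not say how the reporter insertion changes the Il33 transcript or what the sort gates were. The number of animals in each library is not given either.

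Cells were kept with at least 300 genes and at most 10% mitochondrial UMIs. Likely doublets were removed in each library as the highest Scrublet scores, at a rate of 0.8% per 1000 barcodes. In the unsorted lung library 388 of 1870 barcodes failed the filter and 28 were removed as doublets, leaving 1454 cells with a median of 873.5 UMIs. In the reporter-sorted naive lung library 114 of 3598 failed and 104 were removed, leaving 3380 cells with a median of 2680 UMIs. In the reporter-sorted infected lung library 132 of 1751 failed and 25 were removed, leaving 1594 cells with a median of 2157.5 UMIs. In the adipose library 3 of 2037 failed and 33 were removed, leaving 2001 cells with a median of 3787 UMIs.

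The 3 lung libraries were clustered together without batch correction, and the adipose library by itself. Counts were scaled to 10000 per cell and log-transformed. Clusters used 2000 variable genes, 30 principal components, a shared-neighbour graph over 15 neighbours and Leiden clustering at resolution 1.0, with random seed 0. Genes of the fixed lists that are not cell type markers were left out of the variable genes, as were mitochondrial, ribosomal, haemoglobin and sex check genes. This gave 18 lung and 7 adipose clusters. Python 3.11.15 was used with scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, leidenalg 0.10.2, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9.

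Clusters were named from 22 fixed marker lists and are written as "like" a cell type. A cluster took the class with the most markers among its 10 leading genes when at least 3 markers of that class were at least 1.5-fold above the other clusters, on sums with at least 20 UMIs and a pseudocount of 50 CPM (counts of a gene scaled to 1e6 counts of its class sum). It stayed unnamed when another class tied in leading markers, when a class of another lineage had a larger share of its markers raised, or when a shallow cluster had no leading marker. The naming rules were set after the data were seen, and 4 versions were run before the present rule was kept. Clusters left unnamed in which Sftpc held a median of at least 20% of UMIs were read as AT2-like, and any cell with at least 5% Sftpc outside the AT2-like and cycling-like clusters was set apart as AT2-mixed. That limit was also set after the data were seen. Between 2.5 and 10% Sftpc lay 51 of 1387 non-AT2 cells in the reporter-sorted naive library, 29 of 939 in the infected library and 0 of 1405 in the unsorted library. A wide adipose fibroblast class took the clusters without a name and those named as an adipose fibroblast type, where they held at least 5 of 6 general fibroblast markers at 100 CPM or more. The 10 leading genes of the named clusters included immune or stress genes. Examples in lung were Lyz1, Lyz2 and Cd74 in AT2-like clusters, and Ccl2, C7, Mmp3 and Cxcl14 in an alveolar fibroblast-like cluster. Others were Iigp1 in a blood endothelial-like cluster, and C3 and Slpi in the mesothelial-like cluster. In adipose they were Ccl2 in a fibroblast cluster and Slpi, C2 and Trem2 in the mesothelial-like cluster. Scgb1a1, from the marker list of club cells, was the first leading gene of the larger AT2-like lung cluster. No cluster was named club-like. Lymphatic, myofibroblast, pericyte and leukocyte classes were named in the same way. No name could be given to 9.90% of the unsorted, 3.46% of the reporter-sorted naive, 2.32% of the infected and 33.9% of the adipose cells.

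UMIs were summed per library and class with at least 30 cells and given as CPM with exact Poisson 95% intervals. Ratios of CPM carry exact conditional binomial intervals, and shares of cells carry exact Clopper-Pearson intervals. All of these cover counting error only. Log2 ratios used a pseudocount of 10 CPM. Because each group holds 1 library, there was no replicate check, and no p-value or standard error was made from cells. Counts of genes with intervals apart, or of list members called, describe these sums and are not counts of genes changed by a condition. Each comparison compares these libraries and not the conditions. A fold against a class sum of 0 was given as a lower bound against a floor of 3 counts. Shares of cells with a UMI were also computed after thinning each cell to 1000 UMIs and leaving out shallower cells.

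The comparisons, the filters, the gene lists, the marker lists and the rule for named genes were fixed before the data were examined. The rule took, per class and comparison, the 8 highest and 8 lowest log2 ratios among genes with at least 100 UMIs over both sums, at least 50 CPM in the higher sum and Poisson intervals that did not overlap. Mitochondrial, ribosomal, haemoglobin, immunoglobulin, sex check and predicted genes and markers of other classes were left out. Some genes are not reported here. Up to 4 members per list, Il33, Tslp and the sex check genes were added. The 20 lists were ILC2 niche signals, chemokines, type 2 cytokine response, interferon response, antigen presentation, complement, extracellular matrix, mesenchymal growth factors and morphogens, surface proteins of stromal cells, surfactant and lipid synthesis, alveolar epithelial injury state, adipogenesis, Hox genes, regional transcription factors, retinoid pathway, sex steroid and sex-biased adipose genes, immediate early and dissociation stress genes, cell cycle, sex check, and blood and leukocyte background. A member counted as measured with at least 20 UMIs over both sums. It is called higher or lower with a log2 ratio of at least 1 in size and intervals that did not overlap. A list's median log2 ratio is given with its percentile among 10000 random lists of the same size matched on mean expression, as a description of these libraries. Percentiles were computed for lists with at least 5 measured members.

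Some sums rested on single cells holding many UMIs of a gene that other cells of the class held at 1 or 2. After this was seen, sums were recomputed with each count over 5 times the mean of the other cells with a UMI set to that mean (single-cell counts replaced). The rule for named genes was then applied again to those sums, leaving out genes at least 2 times as high in AT2-like cells as in the class. Folds of genes named in this way are given from every UMI unless stated otherwise. Other alternatives chosen after seeing the data were naming by folds over the mean of other clusters or by leading markers alone, clustering without the leading genes of the clusters, leaving AT2-mixed cells in their class, an Sftpc limit of 2.5 or 10%, leaving out the cell with the most UMIs of each gene, leaving out the shallow adipose fibroblast cluster, and comparing adipose with lung mesothelial-like cells. Alternatives planned before the data were examined were every barcode, at least 500 genes and at most 5% mitochondrial UMIs, no doublets or more doublets removed, resolutions of 0.6 and 1.6, each library clustered by itself, leaving out genes over 1% of a sum, median-of-ratios scaling, pseudocounts of 1 and 50 CPM, subtraction of free RNA, equal weight per cell, no UMI minimum and thinning.

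The calling of genes from class sums was tested on simulated sums, with 200 genes changed by 2-fold or 4-fold. These sums were Poisson counts drawn from the pooled profile of the 2 real sums. The intervals assume the same Poisson counts, so the recovery does not cover spread between cells or libraries. Filtering, clustering and naming were not simulated. Among changed genes with enough UMIs, the share recovered at 2-fold was 100% in AT2-like, 96.5% in adventitial and 86.5% in mesothelial-like cells between infected and naive libraries, 100% between adipose and lung fibroblasts, and 86.6% between the sorted and unsorted adventitial classes. At 4-fold it was 100% in each. In separate simulated cells with Poisson counts, 100 of 100 single-cell counts placed were found. A count is found whenever it passes the limit for replacement, so counts placed above that limit are found by construction. This recovery therefore does not show how well single-cell counts near or under that limit would be found.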

Results

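The series measured RNA in single cells, given in the labels as negative for the leukocyte protein CD45, from lung and gonadal adipose tissue of Il33 reporter mice. The series title names adventitial stromal cells as niches of group 2 innate lymphoid cells (ILC2s), tissue lymphocytes that respond to Il33 and Tslp. Each of 4 groups held 1 library. Per the labels these were total CD45-negative cells of naive lung (unsorted library), CD45-negative reporter-positive cells of naive lung (reporter naive library), CD45-negative reporter-positive cells of lung 4 weeks after infection with the nematode Nippostrongylus brasiliensis (reporter infected library), and CD45-negative reporter-positive cells of female naive gonadal adipose tissue (adipose library). The total UMI count was 1758542 in the unsorted library, 9608028 in the reporter naive library, 3836633 in the reporter infected library and 7649922 in the adipose library. The median per barcode was 741, 2668.5, 1979 and 3795 UMIs in the same order. With 1 library per group there was no replicate check, intervals in parentheses are exact 95% intervals that cover counting error only, and every comparison is between these libraries.

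The first comparison asked which cell classes the reporter gate keeps in naive lung. Alveolar type 2 (AT2)-like cells, the surfactant-producing epithelial cells, made up 3.51% of the unsorted library (2.62 to 4.59) and 59.5% of the reporter naive library (57.8 to 61.2) when cells were clustered without the leading genes of each cluster. Mesothelial-like cells, which line the lung surface, made up 0.688% of the unsorted library (10 cells) and 10.03% of the reporter naive library (9.04 to 11.1). The AT2-like share was 17.8-fold higher with all genes used, and 10.04-fold with at least 500 genes and at most 5% mitochondrial UMIs per cell. Alveolar fibroblast-like cells went the other way, with 26.8% of the unsorted library (24.5 to 29.1) and 0.651% of the reporter naive library (0.408 to 0.984), or 30.3% and 1.57% with all genes used. Blood endothelial-like cells made up 35.5% of the unsorted (33.0 to 38.0) and 1.30% of the reporter naive library (0.947 to 1.74). The latter share was 4.97% (4.26 to 5.76) with clusters named by folds over the mean of the other clusters, which gave this name to an otherwise unnamed cluster led by Vwf and Selp. It was 0.414% (0.227 to 0.694) with each library clustered by itself.

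Adventitial fibroblast-like cells, the connective tissue cells of the sheath around vessels and airways, made up 11.4% of the unsorted library (9.83 to 13.2) and 10.6% of the reporter naive library (9.57 to 11.7) in that clustering. With the leading genes used, the shares were 4.195% (3.22 to 5.36) and 9.70% (8.73 to 10.8). Without leading genes the intervals of the shares overlapped, so that clustering gave no direction. With the leading genes used, the share was higher in the reporter naive library, with intervals apart. The leading gene Serpinf1 itself differed between the libraries. Without leading genes the unsorted class grew from 61 to 166 cells, while its Serpinf1 UMIs stayed at 47. Its Ccl2 UMIs went from 4 to 365. The cells added there thus brought no net Serpinf1 UMI. Of 12 alternatives for this ratio of shares, 9 lay within the counting interval of the main value and 2 outside it. The 1 counted as reversed was the clustering without leading genes. Smaller classes in the clustering with all genes included myofibroblast-like cells with 3.99% and 0.0296%, pericyte-like cells with 3.44% and 0.118%, AT1-like cells with 2.41% and 0.296%, and leukocyte-like cells with 5.23% and 0.325% of the unsorted and reporter naive libraries. In the reporter naive library 52 of 56 cells of the pericyte-like cluster and 43 of 53 cells of the AT1-like cluster were set apart as AT2-mixed, so those 2 shares there rest on the cells that remained. So were 51 of 54 cells of an alveolar fibroblast-like cluster led by Gm13889 and 38 of 48 of an endothelial-like cluster led by Car4. The alveolar and endothelial shares with all genes used therefore rest on remaining cells too. With each library clustered by itself AT1-like cells were 7.02% of the unsorted library (5.76 to 8.45). Ptprc, the CD45 gene, was at 795 CPM (599 to 1035) in the unsorted leukocyte-like cells, with a UMI in 37 of 76. This is RNA, while the CD45-negative label refers to the surface protein. Whether these cells carried the protein was not measured. Cycling cells numbered 1 in the unsorted, 6 in the reporter naive and 1 in the infected library. AT2-mixed cells, which are cells with at least 5% Sftpc outside the AT2-like and cycling-like clusters, made up 0.413% of the unsorted library and 13.4% of the reporter naive library (12.2 to 14.6). With clusters named by folds over the mean of the other clusters they were 4.67% of the reporter naive library (3.99 to 5.44) and none of the unsorted library, while AT2-like cells were 67.8% of the former. Their median was 0.188% of UMIs in endothelial markers, against 0.976% in endothelial-like and 0 in AT2-like cells of the reporter naive library. The gate and the depth differed together, since the median kept cell held 873.5 UMIs in the unsorted and 2680 in the reporter naive library.

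**Figure D1:**
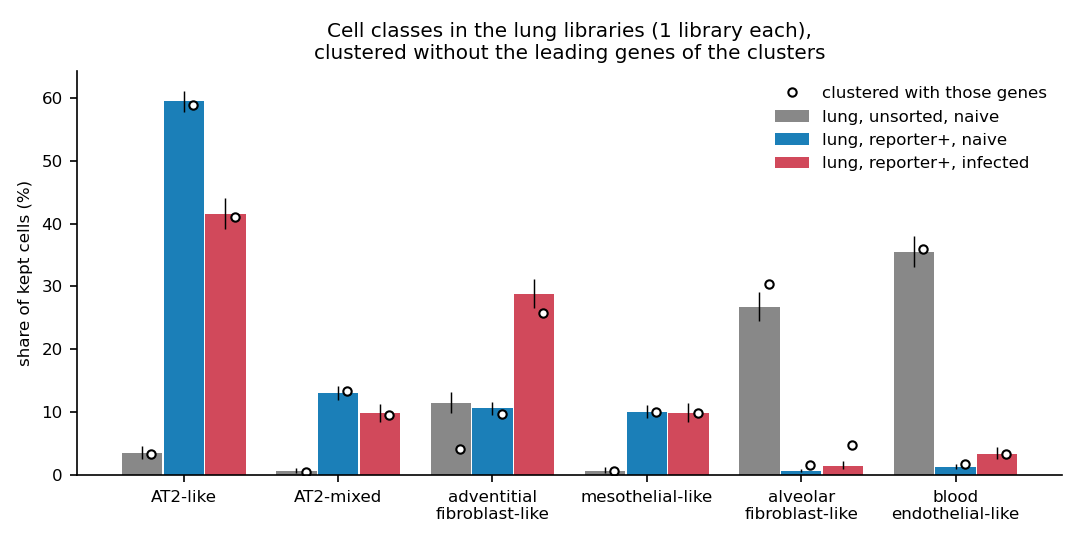
Shares of kept cells (percent) of 6 classes in the 3 lung libraries, with bars from clustering without the leading genes of the clusters, exact 95% intervals as error bars, and open circles from clustering with those genes. AT2-like cells took 3.51% of the unsorted, 59.5% of the reporter naive and 41.5% of the reporter infected library, and adventitial fibroblast-like cells 11.4%, 10.6% and 28.9%. With those genes used the adventitial shares were 4.195%, 9.70% and 25.7%. Without them the intervals of the unsorted and reporter naive libraries overlapped, so the bars give no order for these libraries.

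The next question was which classes hold the transcripts of Il33 and Tslp. Il33 (ENSMUSG00000024810, chromosome 19, 29925114 to 29960718 on the forward strand of GRCm38, 1-based), an alarmin cytokine that activates ILC2s, had its highest value in naive lung in AT2-like cells, with an interval that overlapped that of adventitial fibroblast-like cells. In the unsorted library it reached 219 CPM in AT2-like cells (145 to 316) and 78.1 CPM in adventitial fibroblast-like cells (28.7 to 170, from 6 UMIs). It was at 3.67 CPM in alveolar fibroblast-like cells (0.445 to 13.3, from 2 UMIs), and no UMI was seen in 522 blood endothelial-like cells, where 3 counts would give 6.95 CPM. In the unsorted library the ratio of adventitial to alveolar fibroblast-like cells was 21.3 (3.804 to 216), or 2.69 on the log2 scale with the pseudocount, and 1.14 when clustered without leading genes. In the reporter naive library Il33 was at 159 CPM in AT2-like cells (149 to 169), 143 CPM in adventitial fibroblast-like cells (110 to 183) and 72.8 CPM in mesothelial-like cells (55.1 to 94.3). It was at 47.4 CPM in the 53 alveolar fibroblast-like cells that passed the gate (12.9 to 121, from 4 UMIs) and at 14.7 CPM in endothelial-like cells (0.372 to 81.8, from 1 UMI), a class that leaves out the cluster led by Vwf and Selp.

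A minority of cells in each class held an Il33 UMI, behind a gate set on the reporter protein. In the reporter naive library the share was 30.9% of AT2-like cells (median 2873 UMIs), 12.5% of adventitial (median 1333 UMIs) and 13.9% of mesothelial-like cells (median 2363 UMIs), against 1.64% of 61 endothelial-like cells (median 966 UMIs). After thinning to 1000 UMIs it was 14.2% of AT2-like (12.7 to 15.8, with 37 shallower cells left out), 11.1% of adventitial (7.36 to 15.8, 93 left out) and 7.17% of mesothelial-like cells (4.55 to 10.7, 32 left out). In the unsorted library the share was 31.3% of AT2-like cells (median 2848 UMIs) and 8.20% of adventitial cells (median 1173 UMIs), against 0 of 522 endothelial-like cells (median 696 UMIs, upper bound 0.704%).

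Tslp (ENSMUSG00000024379, chromosome 18, 32815383 to 32819797 on the forward strand), a cytokine that also acts on ILC2s, was in fibroblasts and not detectable above a few UMIs in AT2-like cells. In the unsorted library it was at 75.2 CPM in alveolar fibroblast-like cells (54.0 to 102) and 39.0 CPM in adventitial cells (8.05 to 114, from 3 UMIs), a ratio whose interval includes 1. In the reporter naive library it was at 40.2 CPM in adventitial fibroblast-like cells (23.8 to 63.5) and 47.4 CPM in alveolar ones (4 UMIs), against 0.174 CPM in AT2-like cells (1 UMI). Tslp UMIs were held by 5.18% of adventitial cells there, and by 1.70% after thinning. A value of 350 CPM in unsorted myofibroblast-like cells rested on 1 cell with 17 of the 18 UMIs.

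**Figure D2:**
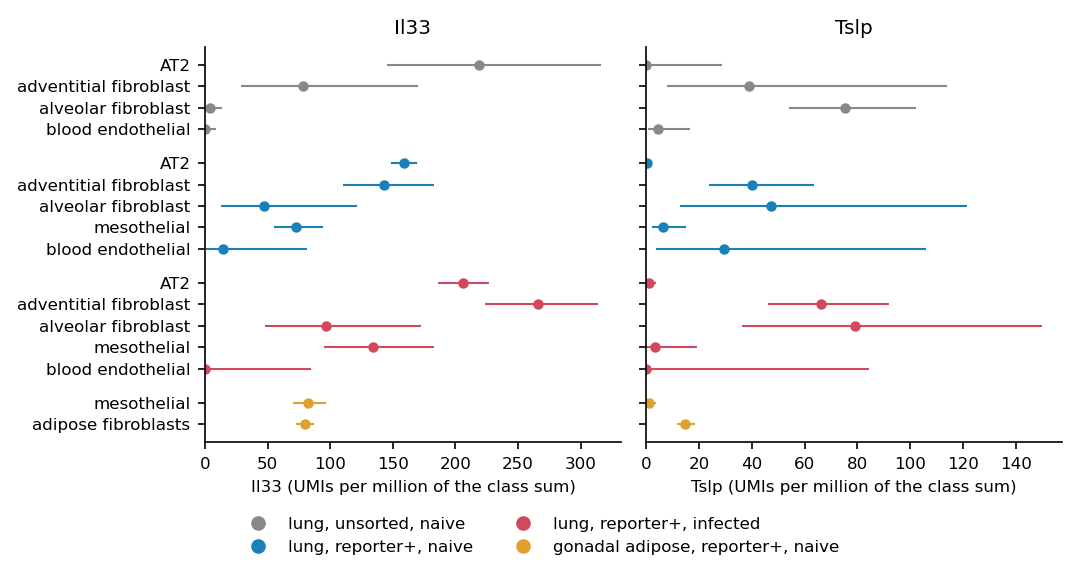
Il33 and Tslp in class sums (CPM, points with exact Poisson 95% intervals) of classes with at least 30 cells in the 4 libraries. In the reporter naive library Il33 was at 159 CPM in AT2-like and 143 CPM in adventitial fibroblast-like cells, and Tslp at 0.174 and 40.2 CPM.

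Other signals separated the classes within the reporter naive library. Adventitial fibroblast-like cells held 10 of 11 measured chemokines at higher levels than AT2-like cells, with a median log2 ratio of 4.16 at percentile 100 of matched random lists. Examples were the eosinophil attractant Ccl11 with 259 against 0.349 CPM (2 UMIs; 742-fold, 201 to 6204), the neutrophil attractant Cxcl1 at 162-fold (125 to 213) and the monocyte attractant Ccl2 at 238-fold (122 to 529). All 10 measured complement genes were higher too (median 5.29), as were 19 of 21 matrix genes (median 4.04), 9 of 16 growth factors and morphogens (median 1.84) and 9 of 12 interferon response genes (median 1.46). Of 10 ILC2 niche signals Il6, Ptgis and Csf1 were higher, and Areg and Ptgs1 lower. Areg, which encodes the epidermal growth factor family member amphiregulin, was 41.1-fold lower (17.6 to 127). AT2-like cells held Cd74 and 5 class II genes at higher levels, with Cd74 119-fold lower in adventitial cells (72.2 to 213). The median of all genes stood at 0.59 on the log2 scale in this comparison of classes, and 16 of 20 immediate early genes were higher in adventitial cells (median 1.79).

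Mesothelial-like cells of the same library carried a different set. Against adventitial fibroblast-like cells, Ptgs1 (cyclooxygenase 1) was 36.4-fold higher (12.3 to 178, from 3 UMIs in adventitial cells), Kitl (stem cell factor) 7.34-fold (4.18 to 14.1), Csf1 3.02-fold (2.01 to 4.70) and Ptgis (prostacyclin synthase) 2.26-fold (1.86 to 2.77). Il6 was 115-fold lower (57.7 to 267) and Tslp 6.30-fold lower (2.25 to 21.7). Of 11 chemokines 9 were lower (median -2.98). The retinoic acid-producing enzyme Aldh1a2 was 54.4-fold higher (23.2 to 168) and the Wnt agonist Rspo1 37.7-fold higher (18.2 to 94.4).

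The 2 fibroblast classes of the unsorted library differed as well. Ccl11 was at 221 CPM in adventitial and 12.9 CPM in alveolar fibroblast-like cells, a ratio of 17.2 (6.79 to 49.1), and Cd34, a surface protein of stromal and endothelial cells, was 7.30-fold higher (4.42 to 12.1). C3 was 2.06-fold higher (1.52 to 2.75), and C1ra and C1s1 were higher among 10 complement genes (median 0.73, percentile 99.5). Lower in adventitial cells were Wnt2 (at least 2.44-fold, with no UMI), the growth factor Fgf7 at 3.72-fold (1.56 to 11.7), Csf1 at 3.28-fold (1.24 to 12.3) and Vcam1 at 2.49-fold (1.74 to 3.71). The median of all genes stood at 0.27 on the log2 scale here. Csf1 missed the size rule when single-cell counts were replaced (log2 ratio -0.92).

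Within classes, the reporter naive and unsorted libraries were then compared. In adventitial fibroblast-like cells, Ccl2 was at 373 against 52.1 CPM in the unsorted library, 7.16-fold higher (2.75 to 26.6). It was the chemokine called higher among 11 (median 0.61, percentile 99.5). Ugdh, an enzyme for hyaluronan precursors, was 3.85-fold higher (2.49 to 6.28), Arpc3 5.72-fold (1.90 to 28.2, from 3 UMIs) and H2afv 2.97-fold (1.32 to 8.29). Hyaluronan synthase Has1, named by the rule on replaced counts, was 2.21-fold higher (1.56 to 3.23) with every UMI. With single-cell counts replaced it was 3.09-fold higher (2.01 to 4.98). The small heat shock protein gene Hspb1 was 4.01-fold lower (2.86 to 5.61), and 2.075-fold lower (1.33 to 3.15) with single-cell counts replaced. Il33 was 1.83-fold higher (0.796 to 5.17) and Tslp 1.03-fold (0.301 to 5.46), with intervals that include 1. These folds depended on which cells the class held, since the class of the unsorted library grew from 61 to 166 cells when clustered without leading genes. That class took in a cluster led by Cxcl1, Ccl7, Has1, Il6, Ccl2 and Ugdh. There Ccl2 went the other way, 2.63-fold lower in the reporter naive library (2.24 to 3.09), Arpc3 was at 1.01-fold (0.737 to 1.39), and Ugdh at 1.501-fold (1.26 to 1.79) and Has1 at 1.59-fold (1.33 to 1.91) missed the size rule. H2afv stayed 2.47-fold higher (1.597 to 3.98) and Hspb1 3.595-fold lower (2.96 to 4.38). Il33 was 5.80-fold higher (2.53 to 16.4), but the unsorted class held 6 Il33 UMIs in either clustering. Spread over the larger class, these fell from 78.1 to 22.8 CPM, so the larger fold came with the added cells. The leading gene Serpinf1 differed in either clustering, at 2.22-fold (1.65 to 3.06) with all genes used. It was at 6.80-fold (5.05 to 9.36) without leading genes, with 47 UMIs in the unsorted class both times. Eif4e, Serinc1, Igfbp5, Mga, Ptov1, Rcn2, Rnh1, Nfic, Atp5k and Dync1i2 were also named by the fixed rule but not when single-cell counts were replaced. The median of all genes moved by -0.14 on the log2 scale.

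In alveolar fibroblast-like cells, Il33 was 12.9-fold higher in the reporter naive library (1.85 to 143, from 2 UMIs in the unsorted library). Spon2 at 3.20-fold (2.27 to 4.47), Igfbp6 at 3.12-fold (2.60 to 3.75), the collagen gene Col1a2 at 2.53-fold (2.11 to 3.02), the complement protease gene C1s1 at 2.46-fold (1.67 to 3.57) and Nbl1 at 2.40-fold (1.97 to 2.92) were higher. Lower were the growth factor gene Bmp5 at 4.64-fold (1.95 to 14.5), Iigp1, a leading gene of a blood endothelial-like cluster, at 4.24-fold (2.11 to 9.94) and Rcan1 at 5.19-fold (1.98 to 19.3). Cxcl10 was 4.07-fold higher (2.08 to 7.74). Of the 10 leading genes of the alveolar class, Itga8, Macf1 and Cxcl14 differed between these libraries. Col1a2 is a leading gene of the adventitial fibroblast-like cluster, as is Nbl1 when clustered without leading genes. Whether the alveolar class held the same cells in both libraries was not tested. The median of all genes stood at 0.14 on the log2 scale. In AT2-like cells Il33 had a ratio of 0.725 (0.498 to 1.10), Il6 was 2.65-fold lower (1.19 to 5.17), and no member of the 19 measured surfactant and lipid genes was called (median 0.13, percentile 95.2). Only 48 AT2-like cells of the unsorted library were available, and 7 of 8 genes named as lower were lost with single-cell counts replaced. In endothelial-like cells Stat2 and Isg15 were among the lower of 15 interferon response genes (median -0.62, percentile 0.445), and Kitl was 2.05-fold lower (1.36 to 3.22). AT2 transcripts entered other classes in the reporter library, where Sftpc (ENSMUSG00000022097) was at 2825 CPM in adventitial and 7170 CPM in alveolar fibroblast-like cells, against 130 and 218 CPM in the unsorted library. Lyz2, which AT2-like cells also express, differed in these classes along with the surfactant genes and is read as that background.

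The infection comparison asked how reporter-positive cells differed 4 weeks after the worm infection. Adventitial fibroblast-like cells made up 10.6% of the reporter naive (9.57 to 11.7) and 28.9% of the reporter infected library (26.6 to 31.2) when clustered without leading genes, and 9.70% and 25.7% (23.6 to 27.9) with them. AT2-like cells made up 59.5% (57.8 to 61.2) and 41.5% (39.1 to 44.0). Mesothelial-like cells held 10.03% (9.04 to 11.1) and 9.85% (8.43 to 11.4), which did not differ beyond counting error. Alveolar fibroblast-like cells held 0.651% (0.408 to 0.984) and 1.44% (0.917 to 2.16), and 1.57% (1.18 to 2.05) and 4.71% (3.72 to 5.86) in the clustering with all genes that the gene comparisons used. Clustered by itself the infected library had no such class. Lymphatic endothelial-like cells held 0.325% and 1.38%, and AT2-mixed cells 13.4% and 9.54% (8.14 to 11.1), in the clustering with all genes. Shares within a gate sum to 100%, so a larger share of one class lowers the others.

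Il33 was higher in the infected library in each of 3 classes, with fold intervals above 1 but under the size rule for list members. It was at 206 against 159 CPM in AT2-like cells, 1.30-fold (1.15 to 1.46), at 266 against 143 CPM in adventitial cells, 1.86-fold (1.38 to 2.54), and at 134 against 72.8 CPM in mesothelial-like cells, 1.84-fold (1.19 to 2.81). A single adventitial cell of the infected library held 35 Il33 UMIs. With such counts replaced the folds were 1.31 (1.17 to 1.48), 1.56 (1.11 to 2.23) and 1.63 (1.04 to 2.54). The mesothelial log2 ratio with the pseudocount was 0.80, and 1.47 with AT2-mixed cells left in their class. The immediate early and dissociation stress list had medians of -0.03, 0.13 and 0.12 in the 3 classes, with no member called by that size rule either. Its members Jun, Junb and Fosb were also higher in all 3 classes, with intervals apart when single-cell counts were replaced. Tslp was at 66.0 CPM (46.0 to 91.8) against 40.2 CPM in adventitial cells, a ratio of 1.64 whose interval includes 1 (0.906 to 3.08). The share of adventitial cells with a Tslp UMI was 7.07% in the infected and 5.18% in the naive library, and 4.01% and 1.70% after thinning.

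In AT2-like cells of the infected library, the cytokine gene Il6 was at 101.5 against 26.5 CPM, 3.83-fold higher (3.08 to 4.76), and it was the member called higher among 9 niche signals (median 0.23, percentile 97.6, or 0.34 with bounds at the floor). Zbtb16, which encodes the transcription factor PLZF, was 2.89-fold higher (2.33 to 3.59). Thbs1, the matrix glycoprotein thrombospondin 1, was 2.25-fold higher (2.03 to 2.51), Wdr89 (ENSMUSG00000045690), also higher in the other 2 classes, 2.19-fold (1.97 to 2.43), Macc1 2.24-fold (1.72 to 2.92), the secreted protease gene Adamts1 2.11-fold (1.73 to 2.58) and Zmym5 2.10-fold (1.70 to 2.58). Lower genes included lipid enzymes, with the fatty acid desaturase Scd2 at 1.73-fold (1.54 to 1.95) and the acyl-CoA thioesterase Acot7 at 1.59-fold (1.42 to 1.79). Tst, Slc25a11, Dpp9, Fkbp4, Nudcd3 and Tsc22d3 were lower by 1.58-fold to 1.83-fold. None of the 19 measured surfactant and lipid synthesis genes reached the size rule, yet their median was -0.17 at percentile 0.445. Of these Scd1 was 1.40-fold lower (1.35 to 1.45) and Fasn 1.36-fold (1.23 to 1.499). The type 2 cytokine response list had 5 measured members, none called (median 0.09, percentile 69.1), and neither did the interferon response (12 members, median -0.02), antigen presentation (14, median 0.12) or injury state list (12, median 0.02) hold a called member. R3hdm1 was named by the fixed rule but not with single-cell counts replaced.

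In adventitial fibroblast-like cells of the infected library, Vcl (vinculin) was at 155 against 44.7 CPM, 3.46-fold higher (2.10 to 5.96), Tpm1 (tropomyosin 1) 2.31-fold (1.76 to 3.07) and Thbs1 2.33-fold (1.91 to 2.85). Cggbp1 was 2.31-fold higher (1.503 to 3.63). With single-cell counts replaced it was higher in all 3 classes. Its log2 ratios there were 0.57 in AT2-like, 1.01 in adventitial and 1.02 in mesothelial-like cells. The rule on replaced counts also named Ccl11 (ENSMUSG00000020676, chromosome 11, 82057823 to 82062955), the eosinophil attractant eotaxin 1. With every UMI it was at 511 against 259 CPM, 1.97-fold higher (1.58 to 2.48). The neutrophil attractant Cxcl2 was 2.07-fold higher (1.42 to 3.07), the laminin gene Lama2 1.93-fold (1.55 to 2.40) and the chaperone gene Hsph1 1.78-fold (1.24 to 2.59). The growth factor gene Bmp5 was 2.44-fold higher (1.38 to 4.51). Lower were the fibrillar collagen genes Col3a1 at 2.15-fold (1.98 to 2.34) and Col1a1 at 2.00-fold (1.82 to 2.19), neither of them in the matrix list, Dnajb9 at 2.64-fold (1.79 to 3.96) and Manf at 2.10-fold (1.63 to 2.72), which was lower in all 3 classes. Hist1h2bc was 2.81-fold lower (1.92 to 4.18) and Tppp3 2.54-fold (1.86 to 3.52). Among the 22 measured genes of the matrix list Thbs1 alone was called, and their median was -0.22 at percentile 0.56. Sparc was 1.85-fold lower (1.72 to 1.99) and the elastin gene Eln 1.62-fold (1.40 to 1.87), both under the size rule, and Sparc was lower in all 3 classes. Chemokines had a median of 0.20 (percentile 90.4) and niche signals 0.23 (percentile 88.9), with no member called before counts were replaced. Nox4, Sltm, Xdh, Swt1, Igfbp5 and Fkbp9 were lost with single-cell counts replaced.

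In mesothelial-like cells of the infected library, matrix genes were lower as a group. The median of 17 measured matrix genes was -0.53 (percentile 0 of matched lists), and -0.45 with single-cell counts replaced. Eln (ENSMUSG00000029675, chromosome 5, 134702593 to 134747323) was at 247 against 742 CPM, 3.001-fold lower (2.35 to 3.89), the collagen gene Col5a2 3.12-fold (1.49 to 7.51) and Sparc 2.12-fold (1.83 to 2.47). Ptgs2, the inducible cyclooxygenase gene, was 2.73-fold higher (1.90 to 3.93), while Hpgd, which encodes a prostaglandin-degrading enzyme, was 2.72-fold lower (1.90 to 4.02). The monocyte attractant Ccl7 was 4.03-fold higher (2.44 to 6.76). Named by the rule on replaced counts, Tnfrsf12a was 2.30-fold higher with every UMI (1.63 to 3.24), the Notch target Hes1 2.13-fold (1.55 to 2.91) and Gadd45b 2.14-fold (1.51 to 3.02). Cd63 at 3.09-fold (2.00 to 4.99), Tax1bp3, Wfdc1, Rcn1 and Pls3 were lower. Slpi was 2.89-fold lower (2.59 to 3.24) and is also a leading gene of this cluster. The interferon response list had a median of -0.44 (percentile 0.86) and antigen presentation 0.40 (percentile 99.7), without a called member in either. Gpatch8, Ndufa9, Spag9, Fam63b, Lsm8, Arl5b and Rnf7 were named by the fixed rule and lost with counts replaced.

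Alveolar fibroblast-like cells (53 naive and 75 infected) and endothelial-like cells (61 and 54) passed the reporter gate in small numbers. In the former, the Wnt modulator Sfrp1 was 3.37-fold higher in the infected library (1.73 to 7.17) and the proteoglycan gene Ogn 1.69-fold (1.32 to 2.18), while Id3 was 1.93-fold lower (1.61 to 2.32) and Ccl7 1.91-fold (1.39 to 2.66). In endothelial-like cells Iigp1, an interferon-induced GTPase and a leading gene of the larger cluster of this class, was at 2903 against 1012 CPM, 2.87-fold higher (2.12 to 3.90), Cd74 3.004-fold (2.04 to 4.47) and Kitl 2.93-fold (1.77 to 4.96). Vcam1 was 14.8-fold lower (2.40 to 608, from 1 UMI against 23 UMIs in 4 naive cells), Fth1 2.46-fold (1.84 to 3.33) and Cst3 2.40-fold (1.56 to 3.82). The interferon response list had a median of 0.61 over 7 members (percentile 97.1), where all genes had a median of 0.15. Surfactant genes had medians of -1.41 in the alveolar fibroblasts and -1.62 in the endothelial-like cells, and Sftpc in the alveolar fibroblasts was at 3205 CPM in the infected and 7170 CPM in the naive library. Adgrf5, Cd93, Plaur, Tax1bp1, Cdh5, Eng, Col6a3, Cpxm1, Ptgs2, Cxcl14 and Uqcrb were called in these classes but not with single-cell counts replaced.

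**Figure D3:**
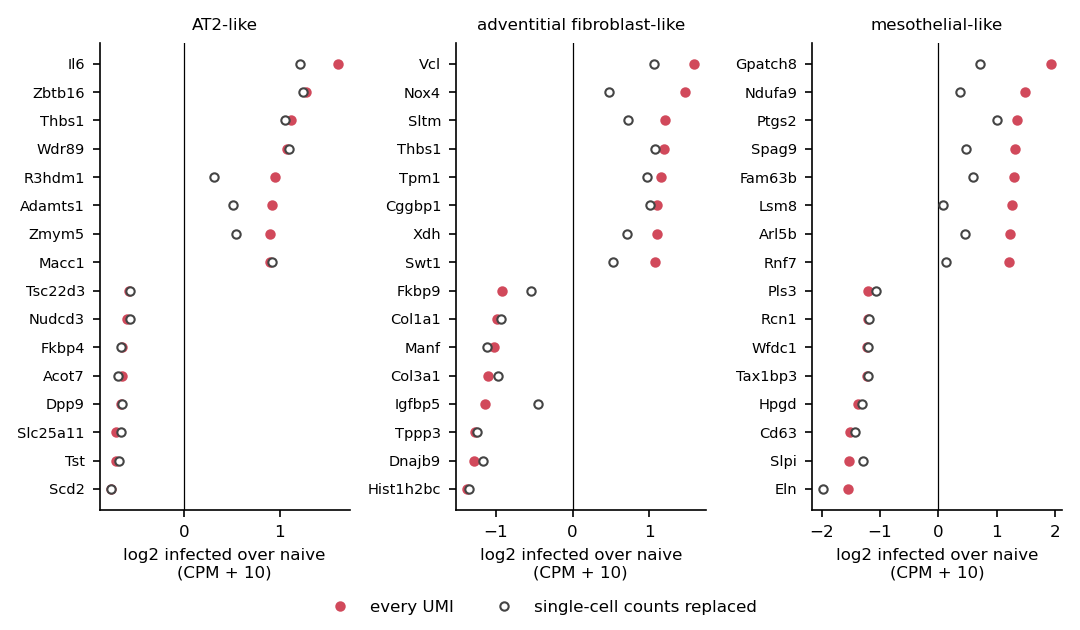
Log2 ratios, infected over naive reporter library, of genes named by the fixed rule in AT2-like, adventitial fibroblast-like and mesothelial-like cells (filled points from every UMI, open points with single-cell counts replaced). Thbs1 was 2.25-fold higher in AT2-like and 2.33-fold higher in adventitial cells, and 7 of the 8 higher genes in mesothelial-like cells were lost with counts replaced.

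The tissue comparison set all 1566 adipose fibroblasts against the 328 adventitial fibroblast-like cells of the reporter naive lung library. Adipose fibroblasts here are the wide class, set by general fibroblast markers, and include a shallow cluster led by Lyz2. Il33 was at 79.6 CPM in adipose (72.3 to 87.3) and 143 CPM in lung, 1.80-fold lower (1.36 to 2.34). Tslp was at 14.9 CPM (11.9 to 18.4) and 40.2 CPM, 2.70-fold lower (1.53 to 4.54). In sums of cells thinned to 1000 UMIs Tslp was no longer called, at 1.15-fold lower (0.347 to 3.02). There it was at 18.5 CPM in adipose and 21.3 CPM in lung (5 UMIs). Thinning also left out shallower cells, and which step moved the ratio was not tested. After thinning, the shares of cells with a Tslp UMI were 1.72% and 1.70%. An Il33 UMI was held by 19.0% of adipose fibroblasts (median 3714.5 UMIs) and by 6.93% after thinning (5.70 to 8.33, with 51 cells left out), against 11.1% in lung. The median of all genes stood at -0.17 on the log2 scale. Tissue and sex were not separated, since the labels give female for the adipose library and the lung libraries held Y-linked transcripts.

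Hox genes, transcription factors that carry position along the body axis, differed in both directions. Of 16 measured, Hoxc9 (ENSMUSG00000036139), Hoxc10 (ENSMUSG00000022484), Hoxc6, Hoxa10, Hoxc8, Hoxc4 and Hoxa9 were higher in adipose and Hoxa5 and Hoxb4 lower. The median was 0.89 (percentile 100), or 0.64 with bounds at the floor, and it ranged from 0.23 to 3.24 between pseudocounts of 50 and 1 CPM. Hoxc9 was at 46.9 CPM with no UMI in lung, at least 7.01-fold higher, and Hoxc10 at 38.2 CPM, at least 5.70-fold. Hoxa5 was 4.98-fold lower (2.71 to 8.78). Among regional transcription factors Wt1 was at least 13.1-fold higher with Tbx18 also higher, while Meox2 was 82.2-fold lower (31.9 to 270) and Foxf1 was at least 116-fold lower, with no UMI in adipose.

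Signals to immune cells differed in kind. Of 12 chemokines 8 were lower in adipose and Cxcl13 and Ccl11 higher (median -1.52, percentile 0.01). Ccl11 was at 866 CPM (842 to 891) against 259 CPM, 3.34-fold higher (2.78 to 4.05), and the B cell attractant Cxcl13 was at least 11.8-fold higher. Cxcl1 was 6.33-fold lower (5.80 to 6.91) and Ccl19 68.5-fold (23.3 to 274). Il6 was at 23.5 against 1170 CPM, 49.8-fold lower (41.1 to 60.8). Of 11 niche signals Il34 (at least 14.1-fold), Ptgs1 (15.6-fold, 5.31 to 75.8, from 3 UMIs in lung) and Ptges (3.14-fold, 1.504 to 7.89) were higher, and Il6, Icosl, Kitl and Tslp lower (median -0.30, percentile 13.1), where the call for Tslp was lost after thinning. Type 2 cytokine response genes had a median of 1.19 over 5 members (percentile 99.9). Of these the matrix protein gene Postn was 11.7-fold higher (7.49 to 19.5), the interleukin 4 receptor gene Il4ra 7.07-fold (3.83 to 14.8) and Il13ra1 3.22-fold (1.46 to 8.87). Complement genes were lower for 5 of 11 (median -0.84), with C7 603-fold lower (255 to 1870). Interferon response genes had a median of 0.44 (5 of 18 higher, Iigp1 lower), and 4 of 12 antigen presentation genes were higher (median 0.68), of which 1 stayed so with counts replaced.

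Genes named by size included, higher in adipose, the phospholipase gene Pla1a at 116-fold (45.3 to 426), the sphingomyelinase gene Smpd3 at 78.7-fold (26.9 to 382, from 3 UMIs in lung), Dact2 at 48.3-fold (13.3 to 399, from 2 UMIs), Sbsn at 31.7-fold (14.6 to 86.5), Krtdap at least 29.6-fold, the Wnt modulator Sfrp2 at 24.99-fold (14.6 to 47.0, with 12 of 13 lung UMIs in 1 cell), the surface protein gene Thy1 at 20.8-fold (9.55 to 56.8) and Lsp1 at 17.3-fold (13.2 to 23.3). Lower were Fmo2 at 137-fold (105 to 181), the matrix protease gene Mmp3 at 121-fold (93.2 to 160), the alcohol dehydrogenase gene Adh7 at 238-fold (118 to 562), Fgl2 at 73.8-fold (51.9 to 108), Maff at 36.4-fold (28.8 to 46.3) and the calcification inhibitor Mgp at 25.04-fold (24.0 to 26.2). Growth factors and morphogens were lower for 12 of 21 (median -1.08, percentile 0), and the retinoid pathway for 4 of 8 (median -1.17), with the retinol carrier Rbp4 31.8-fold lower (25.7 to 39.6) and Aldh1a3 6.39-fold higher (3.72 to 12.0). Of 8 adipogenesis genes the lipid genes Lpl at 4.58-fold (3.50 to 6.09) and Plin2 at 5.95-fold (2.87 to 14.9) were higher and Apoe and Cebpb lower (median 0.25, percentile 59.1). The matrix list held 4 higher and 8 lower genes of 23 (median -0.31), with Fbn1 3.31-fold higher (2.89 to 3.82) and Mfap4 16.2-fold lower (14.4 to 18.3). Surface proteins had 3 higher and 3 lower of 13 (median -0.27), the estrogen receptor gene Esr1 was at least 5.11-fold higher among 3 sex steroid genes, and none of 5 cell cycle genes was called (median 0.44). Immediate early and dissociation stress genes were lower for 18 of 20 (median -2.03, percentile 0), including Egr1 at 4.78-fold (4.41 to 5.17), Fos at 2.34-fold (2.23 to 2.46) and Atf3 at 3.86-fold (3.46 to 4.29). This list moved in the same direction as Il6, Cxcl1, Ccl2 and Maff.

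**Figure D4:**
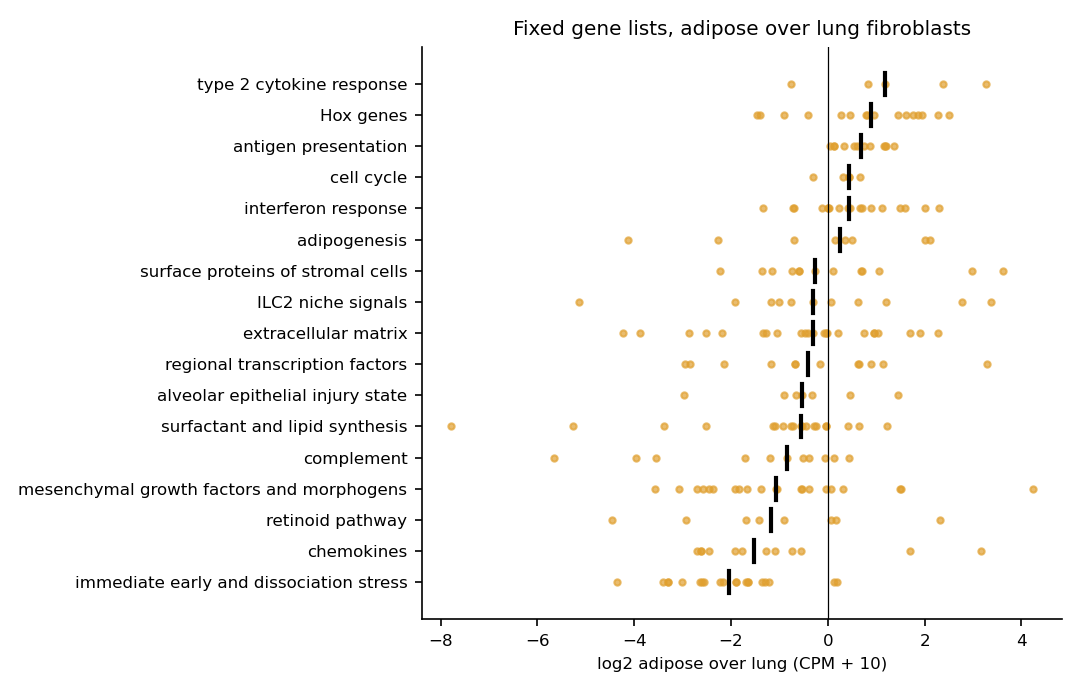
Log2 ratios, adipose fibroblasts over lung adventitial fibroblast-like cells, of measured members of the fixed lists (dots) with each list's median (bar), for lists with at least 5 measured members. The median was 0.89 for Hox genes, 1.19 for the type 2 cytokine response, -1.52 for chemokines and -2.03 for immediate early genes.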

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

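All tests in this part were chosen after the results were seen. Il33 was found in cells that the comparisons left out. It was at 96.1 CPM (53.8 to 158, from 15 UMIs in 107 cells) in a reporter naive cluster led by the endothelial genes Vwf and Selp. That cluster was left unnamed, though naming by folds over the mean of the other clusters calls it blood endothelial-like. It was at 399 CPM (192 to 734, from 10 UMIs) in 22 lymphatic endothelial-like cells of the infected library, a class under the minimum of 30 cells. Both values stood out because they lie above what 3 counts would give in cells outside the comparisons (19.2 and 119.8 CPM). Neither difference between libraries was tested.

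The first pattern weighed was the AT2-mixed cells, 13.4% of the reporter naive library, which lay in other clusters and held at least 5% Sftpc. Their median share of UMIs in AT2 markers was 21.04%, against 31.2% in AT2-like cells. Free AT2 RNA reaches every droplet alike, but at least 5% Sftpc was held by 65.4% of cells with 3 endothelial markers and 9.14% of cells with 3 adventitial markers, a ratio of 7.15, which argues against it. Chance pairing of sorted cells in droplets would hit classes alike too, and the ratio of pericyte-marked to mesothelial-marked cells was 23.5. This cannot exclude chance pairs, because likely doublets had already been removed. Without that removal the reporter naive library held 585 mixed cells, against 452 with it. Both tests chose cells by markers alone, so AT2-like cells could be among them. AT2 cells sorted while attached to neighbouring cells cannot be told apart from other causes, because the unsorted library held few AT2 cells and the result moved with the clustering. Mixed cells were 11.1% of AT2-like and mixed cells together in the unsorted library (4.19 to 22.6, from 6 cells) and 18.5% in the reporter naive library. With each library clustered by itself they were 0 of 50 (0 to 7.11%) and 16.5%. With clusters named by folds over the mean of the other clusters they were 0 of 55 (0 to 6.49%) and 6.45%.

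The second pattern was single cells that held many UMIs of a gene that other cells of their class held at 1 or 2. More UMIs per cell as the cause is argued against, because such counts of 20 or more took 4.53% of UMIs in the library with the lowest median UMIs and 1.63% in the deepest library. Bursts of particular genes cannot be told apart from random events, since 47.6% of such counts in the unsorted library lay in genes with 1 such cell. Misread molecule tags cannot be told apart either, since the counts hold no tags. Such counts of 20 or more took 0.481% of UMIs in the reporter naive library. Apart from bursts, no biological explanation was tested.

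The third pattern was the higher Il33 level in AT2-like, adventitial and mesothelial-like cells of the infected library. Single-cell counts over the replacement limit do not account for all of it within counting error. With them replaced the smallest lower bound of the fold over the 3 classes was 1.04. The adventitial fold fell from 1.86 to 1.56, and the AT2-like fold was 1.30 before and 1.31 after. Counts under the limit were left in, so single cells with several Il33 UMIs are not excluded. Free Il33 RNA from AT2 cells would give at most 2.84% of the difference in adventitial and mesothelial-like cells (1.74 of 61.1 CPM). A stricter reporter gate in the infected sort cannot be told apart from a response to infection, as gate and infection differ together. The share of infected adventitial cells with an Il33 UMI after thinning was 13.7% (10.0 to 18.1), against 11.1% in the naive library (7.36 to 15.8). With single-cell counts replaced, the stress genes Jun, Junb, Fosb and Dnaja1 also had intervals apart and higher values in the same 3 classes. Their log2 ratios lay between 0.09 (Junb, adventitial) and 0.62 (Dnaja1, AT2-like). A difference between the sorts in handling was not tested.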

How the results depend on the processing

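Of 342 alternative values for 18 results, 322 lay within the counting interval of the main value, 19 lay outside it and 1 reversed. Some alternatives could not move a result, such as no UMI minimum for a single gene. A reversal could be counted only where the main interval left out no difference. For Il33 in adventitial cells, sorted over unsorted, log2 ratios of 0.23 to 2.12 all counted as within the interval. These counts are therefore not a measure of stability. Alternatives chosen after seeing the data were clustering without leading genes, the other naming rules, leaving AT2-mixed cells in, the 2.5 and 10% Sftpc limits, replacing single-cell counts, leaving out the cell with the most UMIs and leaving out the shallow adipose cluster. Except where a construction shows it, the cause was not tested. The adventitial share, sorted over unsorted (2.31), was 0.928 without leading genes. That counted as a reversal, though the intervals of the shares overlapped there. It was 1.58 under the stricter filter (at least 500 genes and at most 5% mitochondrial UMIs) and 1.44 with no doublets removed. The AT2-like ratio (17.8) was 10.04 under the stricter filter. The alveolar ratio (0.0517) was 0.0345 under the stricter filter, 0.0168 with each library clustered alone, 0.0243 without leading genes and 0.101 with AT2-mixed cells left in. The log2 ratio of Il33 in mesothelial-like cells, infected over naive (0.80), was 1.47 with mixed cells left in and 1.49 at the 10% limit. The log2 ratio of Tslp class sums, adipose over lung (-1.01), was -0.14 for sums of thinned cells, with the pseudocount of 10 CPM. The shares of thinned cells with a Tslp UMI, a different quantity, were 1.72% and 1.70%. The Hox median (0.89) was 3.24 and 0.23 at pseudocounts of 1 and 50 CPM, by construction near 0 counts, 0.28 without a UMI minimum and 1.58 after thinning. The immediate early median (-2.03) was -2.15 without genes over 1%, -1.83 with median-of-ratios scaling and -1.71 at 50 CPM. Il33, adventitial over alveolar in the unsorted library (2.69), was 1.14 without leading genes. The log2 ratio of thinned shares of cells, a different quantity without the pseudocount, was 4.94. The infected over naive adventitial share (2.65) stayed at 2.48 to 2.82 over 13 alternatives. The log2 ratio of Il33 class sums, infected over naive, stayed at 0.29 to 0.41 in AT2-like and 0.60 to 0.91 in adventitial cells over 23. The shares of thinned adventitial cells with an Il33 UMI were 13.7% (10.0 to 18.1) and 11.1% (7.36 to 15.8), with intervals that overlap. Also stable were the mesothelial matrix median at -0.59 to -0.34, and Il33, adipose over lung, at -1.06 to -0.55 over 24. Depth limits the unsorted library most, where adventitial Il33 rests on 6 UMIs and Tslp on 3. No value was possible for the adventitial sorted over unsorted share with each library clustered alone. No paired analysis was possible because each group has 1 library.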

Other observations

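The comparison of adipose with lung mesothelial-like cells and the count of genes shifted alike in 3 classes were chosen after the data were seen. The adipose library held 78.3% cells of the wide fibroblast class (76.4 to 80.1) and 21.3% mesothelial-like cells (19.5 to 23.1). Fibroblasts of the Dpp4 and Pi16 type made up 35.1% (33.0 to 37.2) and the preadipocyte type 9.70%. No name was given to 33.9% of cells, which fell in the wide fibroblast class apart from 9 cells. That class rests on general fibroblast markers, and the mesothelial-like cluster also held 5 of them at the limit. Of the unnamed cells 252 lay in a shallow cluster led by Lyz2 (median 1594 UMIs), whose identity was not tested further. The finer names of the fibroblast types were unstable. The Dpp4 and Pi16 type ranged from 25.9% without leading genes to 55.8% at resolution 0.6, and 52.8% of cells had no name without leading genes. No preadipocyte type was named in that clustering, with every barcode, with no doublets removed, at resolution 1.6 or by folds over the mean of the other clusters. Il33 was at 81.0 CPM in the Dpp4 and Pi16 type (71.2 to 91.8), 26.6 CPM in the preadipocyte type (15.8 to 42.0) and 82.6 CPM in mesothelial-like cells (70.1 to 96.6). Against adipose fibroblasts, mesothelial-like cells were higher in 7 of 13 antigen presentation genes (median 1.08, percentile 100), with H2-Ab1 at 5.25-fold (4.37 to 6.32), and in 5 of 10 complement genes (median 1.23), with C3 at 3.29-fold (3.17 to 3.40). Cxcl13 was 2.61-fold higher (2.27 to 2.99), Igf1 20.3-fold (18.4 to 22.5) and Gas6 60.1-fold (51.1 to 71.2). Of 11 chemokines 7 were lower (median -1.95).

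Mesothelial-like cells of adipose and lung reporter libraries also differed, where the median of all genes stood at -0.15. Trem2 (ENSMUSG00000023992), a lipid-sensing receptor gene, was at 1276 CPM in adipose against 1.28 CPM in lung (999-fold, 179 to 39490, from 1 UMI in lung), and is a leading gene of the cluster within adipose. Igf1 was 125-fold higher (67.8 to 261), the galectin gene Lgals1 66.6-fold (57.6 to 77.4) and Fgf1 144-fold (56.1 to 529). The water channel gene Aqp1 was 1170-fold lower (457 to 4307) and Sparcl1 257-fold (118 to 704). Of 14 measured Hox genes 11 were higher and Hoxb2 lower (median 1.49, percentile 100), with Hoxa7 at least 19.9-fold higher. Cxcl13 was 53.9-fold higher (18.3 to 262, from 3 UMIs), Dlk1 at least 21.8-fold and the class II gene H2-Ab1 45.5-fold (15.4 to 222, from 3 UMIs). Kitl was 7.19-fold lower (5.29 to 9.92), Csf1 4.83-fold (3.63 to 6.47) and Cxcl10 99.5-fold (38.1 to 370). Immediate early genes were lower for 14 of 20 (median -1.55).

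As a check of sex, Xist was at 742 CPM in the adipose library with no UMI of the 4 Y-linked genes measured, and Ddx3y was at 186, 73.9 and 106 CPM in the unsorted, reporter naive and infected lung libraries. Of 6 blood and leukocyte background genes measured in AT2-like cells, the haemoglobin genes Hbb-bs, Hba-a1 and Hba-a2 were lower in the infected library, and none was with single-cell counts replaced. Genes shifted alike were counted with single-cell counts replaced. Of 1007 genes with at least 100 UMIs in each of AT2-like, adventitial and mesothelial-like cells, 37 had intervals apart between infected and naive libraries in each class. Of these 33 went the same way (19 higher and 14 lower). Those higher included Gm42418 (log2 ratios of 1.08, 1.14 and 1.49 in the order of the classes), Wdr89, Cggbp1, Pabpc1 and Neat1, the stress genes Jun, Junb, Fosb and Dnaja1, and ribosomal pseudogene copies, and those lower included Sparc, Manf and Rps20. A shift shared by epithelial and stromal cells is recorded here beside the named genes Wdr89 and Cggbp1, and whether it came from the library or the infection was not tested.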
